A study of Mus musculus with 6 samples.

How the data were processed

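Small RNA libraries were sequenced from total RNA of primary dermal fibroblasts, 3 caNrf2 and 3 control libraries, each from a different mouse according to the series design. Each deposited file holds raw counts of reads per mature miRNA for 1 library, with 1907 miRNA names, and no normalization is recorded for them. The submitters' processing notes name CASAVA 1.8, cutadapt, Bowtie, featureCounts and edgeR and the mm10 build, without their order or settings, so the handling of reads that fit several precursors and the miRNA annotation release are not given in the sources used here. Reads from identical or near-identical mature sequences can therefore have been split, dropped or counted more than once. No molecular identifiers are named, so counting precision per miRNA covers counting error only.

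Groups and replicate numbers came from the sample labels. Of the 1907 names, 488 had no count in any library. Library totals ranged from 10443268 to 28237159. A value of 3 counts corresponded to 0.106 to 0.287 CPM, and the tested miRNAs held 99.99% of the counts in each library. Library pairs of the same group differed by far more than sampling noise, the lowest chi-square per degree of freedom being 101, so no library was a copy of another. Precursor positions came from the GENCODE M21 annotation of the same build, in which 1849 of the 1907 names matched a precursor.

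miRNAs were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with its minimum count of 10, TMM scaling, glmQLFit and glmQLFTest, group as the only term), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The TMM factors lay between 0.984 and 1.04. SEs of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled. The 16 miRNA lists were fixed before the data were examined, as were the named miRNAs' rule and the design. So were all alternatives except those given below as added after seeing the data. Lists with at least 3 tested members (15 of 16) were tested with camera (limma 3.58.1, preset correlation 0.01, on log2 CPM with a prior count of 2), with camera using an estimated correlation, and with fry, which asks whether a list moves on balance one way without comparing it with other miRNAs. Several lists share members. Shares of counts were compared by two-sided exact permutation tests over 20 assignments.

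The rule named the 10 miRNAs with the largest change in each direction among those called, with a mean of at least 10 CPM and without overlap of the groups, the 5 most abundant miRNAs, and up to 4 members of each list with the smallest p. miR-125b-5p, miR-138-2-3p, miR-150-5p, miR-199a-3p, miR-1a-3p, miR-204-5p, miR-214-3p, miR-218-5p, miR-344-3p, miR-344d-2-5p, miR-344d-3-5p, miR-378a-3p and the other miRNAs brought in among the closing observations were chosen outside that rule, all but miR-138-2-3p, miR-223-5p, miR-342-3p and miR-511-5p after their values were seen. miR-129-1-3p was also chosen outside the rule, after its values were seen. The called miRNAs among those chosen outside the rule were also fitted without each library and with the other scalings. Alternatives were RLE size factors, library totals only, leaving out the 5 most abundant miRNAs, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 10 CPM, a replicate block, leaving out each library, the other list tests, and a share denominator without the most abundant miRNA. Thinning each library to 10443268 counts and the share of the other 4 of the 5 most abundant miRNAs without miR-22-3p in the total were added after seeing the data.

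The tests were checked on counts simulated for the 697 tested miRNAs with the real means, dispersions and library sizes and 200 changed miRNAs. For the caNrf2 comparison edgeR recovered 56.7% of miRNAs changed 1.5-fold, 91.0% of those changed 2-fold and 98.5% of those changed 4-fold, and 1.80% of its calls were false. In a simulated list of 20 miRNAs raised 2-fold, camera with the preset correlation and fry called the list and camera with an estimated correlation did not. The simulated miRNAs were drawn independently of each other. The check therefore does not show how these tests treat lists whose members vary together.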

Results

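Mature microRNAs (miRNAs) were counted in primary dermal fibroblasts from the skin of newborn mice, grown for 6 days and sequenced at passage 1. The fibroblasts of 3 mice carried a constitutively active form of Nrf2 (caNrf2), switched on by a Cre recombinase under the Col1a2 promoter, which is active in fibroblasts. Nrf2 is the transcription factor that drives antioxidant and detoxification genes. Those of 3 other mice carried the Cre alone and served as controls. All mice had a mixed C57Bl/6 and FVB/N background. The counts summed to 10443268, 16446668 and 20595024 in control libraries 1, 2 and 3 and to 13733970, 24163719 and 28237159 in caNrf2 libraries 1, 2 and 3. Between 1050 and 1200 of the 1907 listed miRNAs had at least 1 count in a library. Nrf2 itself is not an miRNA, so these counts give no check of the transgene.

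The comparison asked which miRNAs differ between fibroblasts with active Nrf2 and their controls. The largest rises in caNrf2 fibroblasts were in miR-138, miR-344 and miR-129 species, miRNAs best known from neural tissue. miR-138-5p rose from 63.2 ± 11.7 to 694 ± 84.3 CPM (library-scaled counts, mean ± SD, n = 3 per group), and miR-138-1-3p rose 22.4-fold, from 4.43 ± 1.99 to 96.7 ± 11.8 CPM. miR-344b-3p rose from 6.54 ± 1.66 to 66.4 ± 7.26 CPM, miR-344d-3p 9.28-fold, miR-129-5p 4.06-fold and miR-129-2-3p 3.68-fold. The falls were smaller. miR-5114 fell from 22.5 ± 4.15 to 7.52 ± 0.94 CPM and miR-322-5p, a relative of miR-16 known for restraining the cell cycle, from 3056 ± 246 to 1860 ± 137 CPM.

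Of 697 miRNAs with enough counts to be tested, 98 were higher and 81 lower in caNrf2 fibroblasts at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The change exceeded 2-fold in 42 of the higher and 6 of the lower miRNAs. The CPM ranges of the groups did not overlap for 290 tested miRNAs, or 41.6%, where chance gives 10%. The first principal component of the log2 CPM values held 57.6% of the variance and put the 3 caNrf2 libraries on one side and the 3 controls on the other. When only the 371 miRNAs with a mean of at least 10 CPM were tested, 60 were higher and 71 lower. In the edgeR fit with RLE size factors 91 were higher and 92 lower. The balance of rises and falls therefore depended on these choices.

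**Figure D1:**
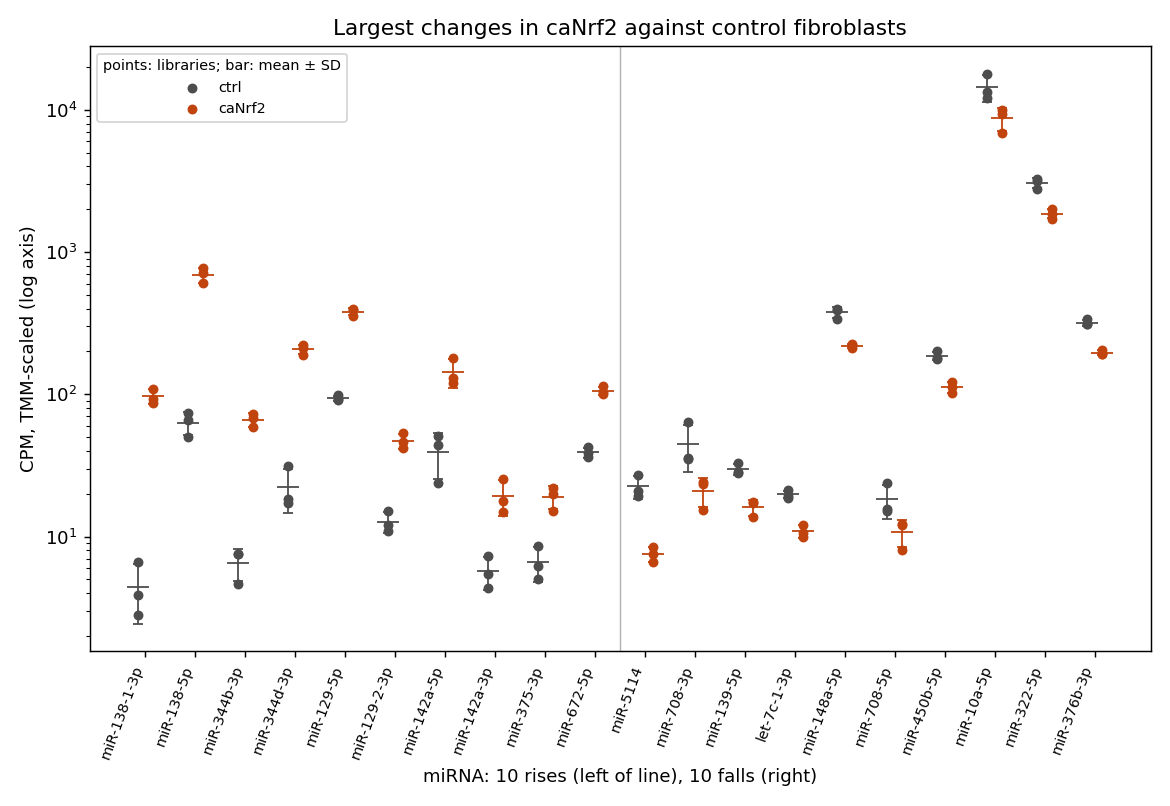
TMM-scaled CPM, on a log axis, of the 10 miRNAs with the largest rise and the 10 with the largest fall among called miRNAs with a mean of at least 10 CPM and no overlap of the groups; each point is a library, and the horizontal bars and error bars give the mean and SD of 3 libraries. The gap is widest for miR-138-1-3p, with means of 4.43 CPM in controls and 96.7 CPM in caNrf2 fibroblasts.

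The precursors of the miRNAs with the largest rises lie on several chromosomes (mm10). miR-138-1-3p, with a log2 fold change of 4.49 ± 0.27 (SE; edgeR adjusted p = 2.07e-06), comes from Mir138-1 at chromosome 9, 122682876 to 122682974, inside an exon of the annotated transcribed pseudogene Gm47135. The 99-base Mir138-1 hairpin reads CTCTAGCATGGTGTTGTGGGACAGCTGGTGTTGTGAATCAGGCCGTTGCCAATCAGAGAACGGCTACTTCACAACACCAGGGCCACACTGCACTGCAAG. miR-138-5p (log2 fold change 3.46 ± 0.15, edgeR adjusted p = 1.46e-07) can also come from Mir138-2 at chromosome 8, 94324311 to 94324381, in an exon of the long noncoding RNA C78859, and its counts do not tell the precursors apart. The chromosome 8 precursor has its own 3p arm, miR-138-2-3p, which had 5 counts over the control libraries and 9 over the caNrf2 libraries. miR-129-2-3p (log2 fold change 1.88 ± 0.17, edgeR adjusted p = 4.16e-05) comes from Mir129-2 at chromosome 2, 94241364 to 94241453, in an intron of Mir670hg. miR-129-5p (2.02 ± 0.09, edgeR adjusted p = 1.46e-07) is shared with Mir129-1 on chromosome 6. The 3p arm of Mir129-1, miR-129-1-3p, had 12 counts over the control libraries and 21 over the caNrf2 libraries. miR-344b-3p (3.33 ± 0.20, edgeR adjusted p = 2.07e-06) comes from Mir344b at chromosome 7, 61790519 to 61790581, in an intron of the long noncoding RNA A230057D06Rik. miR-344d-3p (3.21 ± 0.21, edgeR adjusted p = 3.68e-06) is shared by 3 precursors on the same chromosome.

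Among called miRNAs with a mean of at least 10 CPM and no overlap of the groups, the others of the 10 largest rises were miR-142a-5p (3.60-fold), miR-142a-3p (3.35-fold), miR-375-3p (2.86-fold) and miR-672-5p (2.72-fold). Below 10 CPM, miR-344d-2-5p, miR-344-3p, miR-223-3p and miR-344d-3-5p had larger log2 fold changes than these, 4.34 ± 0.61, 2.37 ± 0.30, 1.90 ± 0.23 and 1.90 ± 0.16, the first from only 2 counts over the control libraries. The miR-142a arms are abundant in blood cells and miR-375 in endocrine cells. miR-672-5p rose from 39.0 ± 3.13 to 106 ± 7.16 CPM (edgeR adjusted p = 2.57e-05) and lies in an intron of Nexmif on the X chromosome. Among the falls, miR-5114 (log2 fold change -1.59 ± 0.18, edgeR adjusted p = 2.28e-04) lies within an exon of Scd2, a fatty acid desaturase gene, at chromosome 19, 44303171 to 44303231. Both arms of miR-708, in an intron of Tenm4, fell, the 3p arm from 44.7 ± 16.3 to 20.97 ± 4.87 CPM. The 5p arm, with an edgeR adjusted p of 0.0295 in all libraries, was no longer called without control library 3 (adjusted p = 0.126), caNrf2 library 1 (0.0533) or caNrf2 library 2 (0.0700). miR-139-5p, let-7c-1-3p, miR-148a-5p, miR-450b-5p, miR-10a-5p and miR-376b-3p fell by 0.89, 0.86, 0.79, 0.73, 0.73 and 0.71 on the log2 scale.

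The 5 most abundant miRNAs held 46.1% ± 0.57 of the counts in control fibroblasts and 51.0% ± 1.15 in caNrf2 fibroblasts (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). miR-22-3p took 17.7% ± 0.14 of control and 22.3% ± 0.92 of caNrf2 counts, a gain of 4.64 points against 4.81 for the 5 together. With miR-22-3p left out of the total, the other 4 held 34.6% ± 0.60 and 36.9% ± 1.54 (exact permutation p = 0.2). The log2 fold change of miR-22-3p was 0.31 ± 0.10 (edgeR adjusted p = 0.0349). The call was lost in the edgeR fit with RLE size factors (adjusted p = 0.0703). It was also lost without any one library other than control library 1 (adjusted p from 0.0675 to 0.115). miR-10b-5p, which lies in an intron shared by Hoxd3 and Hoxd4 on chromosome 2, fell from 4.64% ± 0.17 to 3.19% ± 0.29 of the counts (log2 fold change -0.56 ± 0.10, edgeR adjusted p = 0.00245). miR-21a-5p, a miRNA abundant in activated fibroblasts, had 10.7% ± 0.25 and 11.1% ± 1.23 of the counts and a log2 fold change of 0.03 ± 0.12 (edgeR adjusted p = 0.861). miR-143-3p (0.28 ± 0.09, edgeR adjusted p = 0.0512) and let-7i-5p (-0.27 ± 0.09, edgeR adjusted p = 0.0605) did not pass the threshold, but each passed it in the same direction in 7 of 14 alternatives, with adjusted p from 0.00696 to 0.0467 for miR-143-3p and from 0.0273 to 0.0464 for let-7i-5p.

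The miR-29 family, known for repressing collagen and other matrix genes, was higher in caNrf2 fibroblasts. Of its 7 tested members 6 rose over all miRNAs tested, and 7 adjusted over the list alone, with a median log2 fold change of 0.81. The median was that of miR-29b-1-5p, which stayed below 10 CPM in both groups, as did miR-29c-5p and miR-29b-2-5p. Together the family held 0.735% ± 0.038 of the control and 0.962% ± 0.047 of the caNrf2 counts (exact permutation p = 0.1). The members come from the clusters Mir29b-2 to Mir29c on chromosome 1 and Mir29a to Mir29b-1 on chromosome 6. Their rises are therefore not independent. miR-29c-3p rose 1.96-fold, from 56.4 ± 4.80 to 111 ± 4.05 CPM, and miR-29c-5p rose 2.07-fold. miR-29a-3p, the most abundant of those named here, rose 1.28-fold, from 7116 ± 391 to 9112 ± 602 CPM (edgeR adjusted p = 0.0106), and lost its call without caNrf2 library 2 (adjusted p = 0.0577) or 3 (0.0516). The set test camera with a preset correlation put the family above the other miRNAs (adjusted p = 0.00151 over 15 lists), and the call was lost at an adjusted p of 0.329 with an estimated correlation.

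Of the 12 tested miRNAs associated with fibrosis and TGF-beta signalling, 5 fell and none passed as higher at the threshold over all miRNAs, while 5 fell and 2 rose adjusted over the list alone. The list had a median log2 fold change of -0.33 and did not pass camera (adjusted p = 0.0986). The falls were in the miR-199 species and miR-214-5p, known from mesenchymal cells and fibrotic tissue. The more abundant arm miR-214-3p had 3379 ± 102 and 2811 ± 727 CPM and did not pass (log2 fold change -0.27 ± 0.15, edgeR adjusted p = 0.231). miR-199a-5p fell from 8305 ± 751 to 5849 ± 382 CPM, miR-199b-5p from 460 ± 34.95 to 336 ± 9.31 CPM and miR-214-5p from 1559 ± 56.0 to 1055 ± 70.5 CPM. The miR-199a-3p and miR-199b-3p counts kept a ratio of 1.48 to 1.496 in all 6 libraries. Their sequences are identical, so their separate levels are uncertain and their falls are not separate observations. The Mir199a-2 and Mir214 precursors also lie in 1 cluster on chromosome 1, so the 5 falls are not independent. miR-199b-3p (edgeR adjusted p = 0.0126) also lost its call without caNrf2 library 1 (adjusted p = 0.0559) or control library 3 (0.0553). So did miR-199a-3p (0.0140 in all libraries, 0.0608 and 0.0611 without these).

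Of 9 tested miRNAs reported to respond to Nrf2, 4 rose and 2 fell, and 5 rose and 2 fell adjusted over the list alone. The list does not record the reported direction of each response. Its counts and set test therefore do not show whether the changes follow the reports. The rises over all miRNAs were in miR-129-5p, miR-129-2-3p, miR-206-3p and miR-29a-3p. The falls were in miR-378a-3p, from 7476 ± 1134 to 5262 ± 747 CPM (edgeR adjusted p = 0.0149), and miR-125b-5p, from 10532 ± 1768 to 8084 ± 236 CPM (0.0299). The miR-378a-3p call was lost without control library 3 (adjusted p = 0.0637) or caNrf2 library 1 (0.0558), and that of miR-125b-5p without control library 2 (0.0656, log2 fold change -0.24 in place of -0.38) or any one caNrf2 library (0.0595 to 0.0689). The list held 2.54% ± 0.22 of the control and 2.35% ± 0.06 of the caNrf2 counts (exact permutation p = 0.3). miR-206-3p rose 2.07-fold, from 3.86 ± 0.73 to 7.93 ± 0.62 CPM. The median log2 fold change was 0.36 (camera adjusted p = 0.0851, but 0.0424 with no filter and 0.0483 in thinned counts; 0.329 with an estimated correlation), and 2 of the risen members also belong to the miR-29 and muscle lists. Among 10 tested miRNAs reported to target Nrf2 or Keap1, its inhibitor, miR-142a-5p and miR-27b-3p rose, both also adjusted over the list alone (camera adjusted p = 0.815). These 2 of 10 are a smaller share than the 25.7% called over all tested miRNAs. Since the list pools both targets, it has no single reported direction. miR-27b-3p rose 1.29-fold (edgeR adjusted p = 0.0183) and lost its call without control library 2 (adjusted p = 0.0758), control library 3 (0.0774), caNrf2 library 1 (0.0557) or caNrf2 library 2 (0.0709).

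The Dlk1-Dio3 imprinted cluster on chromosome 12, one of the largest mammalian miRNA clusters, was lower in caNrf2 fibroblasts. Of the 88 tested miRNAs listed for it, 14 fell and 1, miR-666-3p, rose, over all miRNAs and adjusted over the list alone. Their median log2 fold change was -0.17. Over all 697 tested miRNAs 98 rose and 81 fell (25.7%), a larger share of calls than in the list but a smaller share of falls. The list leaves out the miR-341 arms and miR-1188-5p of the same stretch. With these, 6 of 26 tested miRNAs fell from Mir770 to Mir370 and 9 of 65 from Mir379 to Mir3072. Together the listed miRNAs of the cluster held 9.09% ± 0.67 of the control and 7.40% ± 0.42 of the caNrf2 counts (exact permutation p = 0.1, adjusted over the lists 0.178). miR-376b-3p fell from 319 ± 15.9 to 196 ± 7.39 CPM, miR-134-5p from 897 ± 26.6 to 632 ± 40.9 CPM and miR-411-5p from 14081 ± 570 to 10387 ± 267 CPM. miR-666-3p rose from 89.9 ± 7.11 to 135 ± 9.97 CPM. Camera called the cluster lower with a preset correlation (adjusted p = 8.56e-05), and the call was lost at an adjusted p of 0.329 with an estimated correlation.

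**Figure D2:**
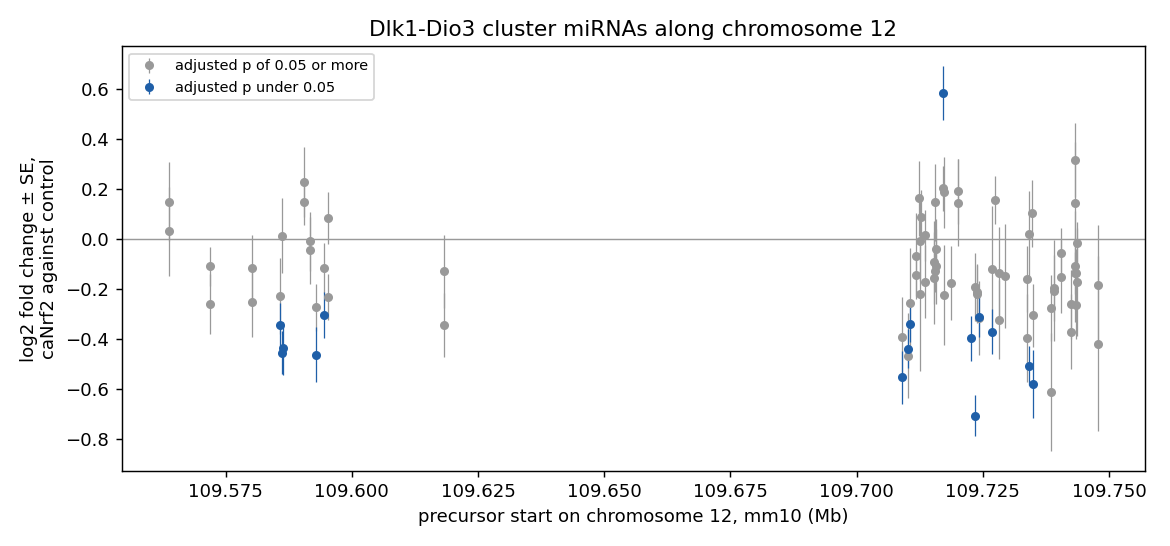
Log2 fold change (caNrf2 against control, with its SE) of the 88 tested miRNAs listed for the Dlk1-Dio3 cluster. It is drawn against the start of each miRNA's precursor on chromosome 12 (mm10, Mb). Tested miRNAs of the same stretch that the list leaves out are not drawn. Filled blue points passed the test and grey points did not. Most points lie below 0, and miR-666-3p is the 1 blue point above it.

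The Hox cluster miRNAs also held called falls. For comparison with the counts below, 25.7% of all tested miRNAs were called. The share was smaller in the let-7, p53, stress, miR-17-92 and Sfmbt2 lists. Of 5 tested, miR-10a-5p and miR-10b-5p fell over all miRNAs and 3 fell adjusted over the list alone, the third being miR-196a-5p (log2 fold change -0.26 ± 0.10, edgeR adjusted p over all miRNAs 0.0873). The list did not pass camera (adjusted p = 0.160). In the let-7 and miR-98 list, let-7b-5p fell by 0.50 and let-7c-5p by 0.34 on the log2 scale among 10 tested, and both also passed adjusted over the list alone (camera adjusted p = 0.207). Of the 11 tested p53-induced and senescence-associated miRNAs, miR-146a-5p (1.84-fold) and miR-22-3p rose, both also adjusted over the list alone (camera adjusted p of the list 0.439). miR-34a-5p had a log2 fold change of -0.23 ± 0.10 (edgeR adjusted p = 0.137) and passed in no alternative. miR-34c-5p (0.29 ± 0.11, edgeR adjusted p = 0.0755) and miR-34c-3p (0.47 ± 0.20, 0.106) went the other way. They passed in 3 of 15 and 2 of 14 alternatives. As given for miR-22-3p above, its call was not kept with RLE size factors (adjusted p = 0.0703). Among 10 tested miRNAs of hypoxia, inflammation and stress, miR-223-3p and miR-146a-5p rose, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.465). Among the 9 tested arms listed for the miR-17-92 cluster and its paralogs, miR-17-5p alone rose, on both adjustments (1.26-fold, edgeR adjusted p = 0.0216). Camera did not call the list (adjusted p = 0.439). The miR-17-5p call was lost without any one library other than control library 1 (adjusted p from 0.0549 to 0.106). With unlisted arms, 2 of 8 tested miRNAs from Mir17 to Mir19b-1 on chromosome 14 rose, and all 8 had a positive log2 fold change. Of 37 tested miRNAs from the Sfmbt2 cluster families, miR-297b-5p passed over all miRNAs at a mean of 0.67 CPM and none passed adjusted over the list alone (camera adjusted p = 0.439). miR-297b-5p was not called by DESeq2 (adjusted p = 0.0800) or without control library 3 (0.0510) or caNrf2 library 2 (0.0505).

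Some markers of other cell types moved with the genotype. All 5 tested muscle miRNAs rose, on both adjustments, with a median log2 fold change of 1.05 (camera adjusted p = 0.00151; adjusted p = 0.329 with an estimated correlation). miR-133a-3p rose from 371 ± 38.9 to 614 ± 90.3 CPM, while miR-499-5p reached only 2.90 ± 0.04 CPM. miR-1a-3p, the main miRNA of muscle fibres, had 9 counts over the control and 16 over the caNrf2 libraries. Of 7 tested blood cell miRNAs 4 rose, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0898). Camera called the blood list with no filter (adjusted p = 0.0381), at a mean of at least 10 CPM (0.0288) and in thinned counts (0.00914), all with the preset correlation, but not over all libraries with an estimated correlation (0.622). The risen miRNAs included miR-142a-5p, from 39.6 ± 14.1 to 143 ± 33.1 CPM, miR-223-3p, from 4.01 ± 0.97 to 15.3 ± 3.76 CPM, and miR-486a-5p, from 386 ± 32.5 to 534 ± 47.7 CPM. The lymphocyte miRNA miR-150-5p had a log2 fold change of -0.10 ± 0.17 (edgeR adjusted p = 0.693). Of 6 tested neural, Schwann cell and melanocyte miRNAs, miR-138-5p, miR-9-5p and miR-338-3p rose, on both adjustments (camera adjusted p = 0.0859, and 0.0483 in thinned counts; 0.329 with an estimated correlation). The other members, miR-211-5p, miR-204-5p and miR-218-5p, had log2 fold changes of 0.25 ± 0.22, 0.17 ± 0.25 and 0.04 ± 0.12 (edgeR adjusted p = 0.448, 0.645 and 0.821). The miR-9-5p call (edgeR adjusted p = 0.0219) was lost without control library 1 (adjusted p = 0.0613) or any one caNrf2 library (0.0527, 0.0687 and 0.0606 without libraries 1, 2 and 3), and that of miR-338-3p (0.0204) without control library 1 (0.0644) or caNrf2 library 2 (0.0818) or 3 (0.0779). None of 10 tested keratinocyte and epithelial miRNAs passed by edgeR, all with a positive log2 fold change and a median of 0.36 (camera adjusted p = 0.207, and 0.00807 without caNrf2 library 1; 0.771 over all libraries with an estimated correlation). Of these, miR-205-5p, a main keratinocyte marker, had a log2 fold change of 0.54 ± 0.19 (edgeR adjusted p = 0.0590) and passed in 6 of 15 alternatives, among them DESeq2 (adjusted p = 0.0209), limma-voom (0.0319) and the edgeR fit without control library 1 (0.00205). The endothelial miR-126a-3p and miR-126a-5p had log2 fold changes of 0.17 ± 0.14 and 0.23 ± 0.15 (edgeR adjusted p = 0.389 and 0.295).

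**Figure D3:**
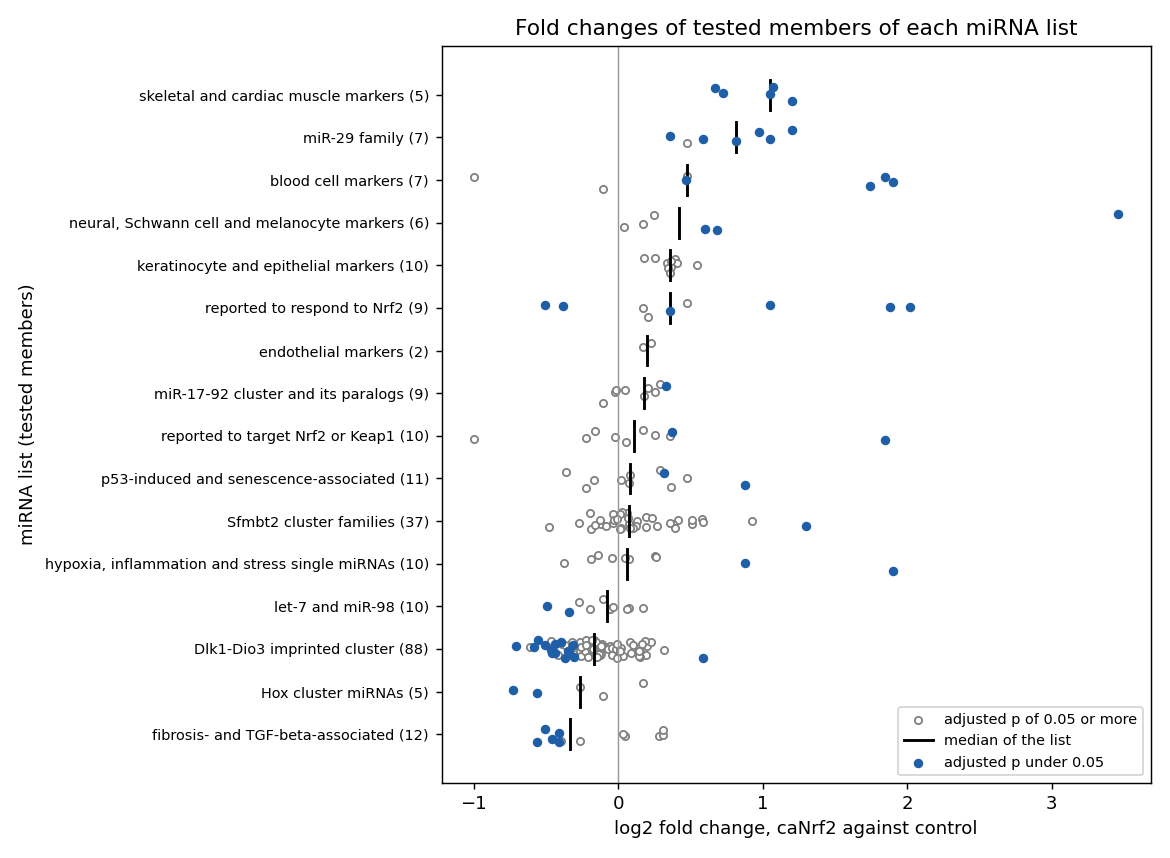
Log2 fold change (caNrf2 against control) of the tested members of each of the 16 miRNA lists; filled points passed the edgeR test over all miRNAs, open points did not, black bars are list medians and numbers in parentheses count tested members. The muscle and miR-29 lists have the highest medians, 1.05 and 0.81, and the list associated with fibrosis and TGF-beta signalling has the lowest, -0.33.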

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

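Thinning the libraries to equal totals and the share of the other 4 of the top 5 without miR-22-3p were chosen after seeing the data; the other alternatives were planned. The number of changed miRNAs was 179 and lay between 131 and 211 under other scalings, tests and filters, with between 120 and 177 of the calls shared and all shared calls in the same direction. Leaving out 1 library gave 126 (without control library 3) to 174. The split of 98 higher and 81 lower became 60 and 71 when a mean of at least 10 CPM was required, which left 371 miRNAs to test, and 91 and 92 with RLE size factors. The 3 lists that passed camera became 5 without a filter, 6 in thinned counts, 0 with an estimated correlation and 9 with fry, which asks a different question; the cause was not tested for the first 2. Replicate numbers did not pair the libraries, since the deviations of same-numbered libraries correlated at 0.18, 0.11 and -0.22 and not every library correlated best with its own number. The fit with the replicate block called 189 miRNAs. Without miR-22-3p in the total, the group differences in share moved for 9 of 16 lists, and 0 changed sign. The difference of the p53 list went from 4.74 to 0.166 points. miR-22-3p belongs to that list and was left out of its counts as well as of the total. Of the 47 named miRNAs that were called, 9 lost their call in at least 1 of 15 alternatives, and none changed direction. Of the 25 that were not called, 12 gained a call in at least 1 alternative. Equal totals left 621 miRNAs to test in place of 697 and 169 calls, of which 162 were shared.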

Other observations

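Of the tests below, only those of miR-138-2-3p and of the further myeloid miRNAs were set before their result was seen; the others were chosen after the result, or a closely related one, was seen. The other miRNAs and the clusters in this part were chosen after their values were seen. In a few genomic clusters most of the tested miRNAs moved in the same direction. In the X-linked cluster from Mir450b to Mir322, 6 of 10 tested miRNAs fell, with miR-503-5p lower by a log2 fold change of -0.96 ± 0.15 and miR-351-5p by -0.43 ± 0.08 (edgeR adjusted p = 0.00129 and 0.00367). In the chromosome 16 cluster of miR-99a, let-7c and miR-125b, all 6 tested miRNAs fell, with miR-99a-5p going from 292 ± 25.5 to 195 ± 29.9 CPM (SD, n = 3); let-7c-5p and miR-125b-5p also have precursors elsewhere. In the chromosome 7 family all 6 tested miR-344 miRNAs rose by edgeR, among them miR-344-3p, from 22 to 163 counts per group, and miR-344d-3-5p, from 102 to 545. The hypothesis that miRNAs of one genomic cluster change together was tested over 426 precursors, on pairs of neighbours within 10 kb from different families. Of 97 pairs, 61 deviated to the same side of the median. The mean product of their deviations was 0.059, above every value obtained by flipping signs at random (permutation p = 1.000e-04, the smallest that 9999 permutations can give), and 55 of 86 pairs did so without the Sfmbt2 families (p = 1.000e-04). An earlier form of the test, which shuffled values among all precursors, was replaced because it could not tell shared change from clusters with little change. The hypothesis fits but was found and tested on the same data. The chromosome 12 clusters from Mir770 to Mir370 and from Mir379 to Mir3072, with 14 and 36 precursors, were not left out. How far the result rests on them was not tested. The test also does not tell a response to the genotype from any other shared variation of neighbours.

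Other called miRNAs of moderate abundance were miR-149-5p, which rose from 342 ± 29.9 to 683 ± 86.0 CPM, miR-877-5p, which rose 1.79-fold to 231 ± 6.53 CPM, and miR-335-5p, which rose from 142 ± 23.6 to 266 ± 17.5 CPM. miR-140-3p, known from cartilage and fibroblasts, fell from 3245 ± 145 to 2075 ± 80.7 CPM and miR-148a-3p from 14799 ± 989 to 9576 ± 509 CPM.

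The real grouping called 179 miRNAs, and the highest of the other splits of the 6 libraries into 3 and 3 called 1. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

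For the rise of 10 called miR-138, miR-129 and miR-344 miRNAs, the 8 tested in thinned counts had a median log2 fold change of 2.66. The median of all 10 was 2.79 in the full counts. Random thinning keeps each miRNA's expected share of its library. It can therefore hardly move a fold change and does not decide whether depth played a part. In caNrf2 fibroblasts miR-124-3p, the most abundant neuronal miRNA, stood at 0.12 CPM while miR-138-5p gained 631 CPM. Such values would argue against neurons in the cultures. A loss of miR-124-3p reads in counting was not excluded, so this marker does not decide the question. Melanocytes are argued against by miR-211-5p and miR-204-5p, which together gained 1.19 CPM. Schwann cells were not tested, and miR-338-3p, a glial miRNA, went from 17.4 ± 2.48 to 26.5 ± 3.61 CPM. A contribution of both miR-138 precursors is argued against by the 9 counts of miR-138-2-3p in the 3 caNrf2 libraries, unless that arm is unstable, which was not tested.

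For the rise of muscle and blood cell miRNAs, the 9 called members had a median log2 fold change of 1.05 in thinned counts (1.07 before). Since thinning keeps expected shares, this does not decide on depth either. In caNrf2 fibroblasts miR-1a-3p stood at 0.22 CPM while miR-133a-3p gained 243 CPM, which would argue against differentiated muscle fibres. In controls, however, miR-1a-3p already stood at 0.23 CPM beside 371 CPM of miR-133a-3p. A loss of miR-1a-3p reads in counting was not excluded, so this marker does not decide the question. Undifferentiated myoblasts, which hold little miR-1a-3p, were not excluded either. More myeloid cells in the caNrf2 cultures cannot be told apart from a change within the fibroblasts. Of 3 further myeloid miRNAs set for the test, miR-511-5p and miR-342-3p had enough counts, with a median log2 fold change of 0.56, between the bounds set for and against, and miR-342-3p already stood at 185 CPM in controls. In favour of more myeloid cells, miR-511-3p, left out of that test because its rise had been seen, had a log2 fold change of 1.77 ± 0.23 (edgeR adjusted p = 4.80e-04), and miR-223-5p went from 5 to 37 counts per group.

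A few abundant miRNAs taking more of the counts would lower the Dlk1-Dio3 cluster and the other miRNAs alike. The median log2 deviation of the miRNAs listed for the cluster was taken relative to that of the 609 tested miRNAs outside the list. The 609 include the tested miRNAs of the same stretch that the list leaves out. The relative deviation was 0.11 ± 0.09 in control and -0.12 ± 0.08 in caNrf2 libraries (SD, n = 3). No scaling factor can move the difference of -0.23. The groups did not overlap, but control library 1 (0.009) and caNrf2 library 1 (-0.031) lay close together. The difference argues against abundant miRNAs taking more of the counts as the whole cause. The median log2 fold change of the listed miRNAs was -0.17 in thinned counts, as in the full counts. Since thinning keeps expected shares, this does not decide on depth. For these 3 patterns the genotype stays open, and no test here bears on how it would act.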
